A study of Drosophila melanogaster with 4 samples.

How the data were processed

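Total RNA was extracted with Trizol from pupal eye discs, and biotin-labelled cRNA from each sample was hybridised to an Affymetrix Drosophila Genome 2 array, 1 sample per array, per the labels' protocols. There were 2 control arrays (GMR-Gal4) and 2 Yki overexpression arrays (GMR-Gal4 with UAS-Yki). Groups and replicate numbers were taken from the sample titles. The deposited table holds a linear intensity for each of 18952 probe sets on each array. Per the submitters' processing notes the authors used Affymetrix Expression Console, and the series design text names the Affymetrix operating software and dChip for pairwise comparisons between the groups. The algorithm that summarised the probes, its settings and its detection calls are not given in the sources used here. In the deposited intensity values the mean after trimming 2% of probe sets at each end lies between 500.01 and 500.013 on every array, so the arrays had been scaled to a common target. They had not been log transformed, and their medians differ from array to array. No column of the table was left unused (0).

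Probe sets were named through a platform annotation, whose gene identifiers were matched to a RefSeq gene table (assembly Release 6 plus ISO1 MT). Of all probe sets, 183 were control probe sets, 13647 had 1 gene symbol, 402 had several and 4720 are unnamed here. Of those with 1 gene, 13544 matched the RefSeq table, which changed no symbol (0), and 103 kept the platform's symbol. Probe sets with several genes or none were tested as probe sets but named no gene. No coordinates are given, and the test of neighbouring genes took only the order of genes from the RefSeq table.

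The main test used limma 3.58.1 in R 4.3.3, with lmFit and eBayes on log2(intensity + 16) and the group as the only term, over the 18769 non-control probe sets. The Benjamini-Hochberg adjustment was applied over all of them and calls were made at an adjusted p under 0.05. The residual degrees of freedom were 2, to which the moderation added 3.03. A fold change is on the log2(value + 16) scale, which understates the change of dim probe sets. For genes, the probe set with 1 symbol and the highest mean over the 4 arrays stood for the gene, and the adjustment was repeated over 11982 genes. As a description, probe sets were counted for which both Yki arrays lay at least 2-fold above or below both control arrays on the same log2 scale. Values are given as means ± SD of the deposited intensities.

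Before the data were examined, 36 gene lists were fixed for Yki targets and Hippo signalling, other signalling, the cell cycle and growth, eye and neuronal differentiation, mitochondria, metabolism, cuticle and timing, stress and immunity, and markers of other tissues. In the cuticle list a name pattern that also took in eggshell and other genes was removed after the table was opened and before any test. The lists hold 1007 entries for 943 measured genes, 60 of them in more than 1 list. Lists with at least 5 measured members were tested with limma's camera at its preset correlation of 0.01, with an estimated correlation, and with fry, with the adjustment over the 36 lists. camera compares a list with all other genes, and fry asks whether its members move, on balance, one way. The mixed form of fry, which asks whether members move in either direction, was also run, without adjustment over the lists. Members were also tested with the adjustment over the list alone.

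Genes were named in the text by a rule fixed before the data were examined. The rule took yki, then up to 10 rises and 10 falls by size among called genes whose groups do not overlap, then up to 4 members per list past the threshold over the list alone by size, or the 2 with the smallest unadjusted p where none passed. It always took th (now Diap1), CycE, ex, fj, kibra, Myc, Opa1, Marf, Sod2, ninaE and elav, of which Diap1, Myc and ninaE were not analysed here. Members that decide a weighed pattern came in addition. GstD9 and Prx6a fall outside it and were named after their values were seen.

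The pipeline was tested on simulated data, drawn from the means and residual SDs of the real probe sets, with 4 arrays and 200 of 18769 probe sets changed. In 20 runs it recovered 0% of changes of 1 log2 unit, 1.87% of changes of 2 and 51.3% of changes of 4, and 5 of 707 calls were false. A simulated list shifted by 1 log2 unit was found in 20 of 20 runs by camera with the preset correlation and in 0 of 20 with an estimated correlation, while 0 unshifted lists were called. The simulated probe sets varied independently, whereas the estimated correlation within the real lists ran from -0.09 (JAK/STAT signalling) to 0.60 (complex I). The runs therefore cannot show how often the preset correlation passes unshifted lists of correlated genes.

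The replicate numbers come from the labels, which do not say that a number marks a shared batch. Deviations from the group means of arrays with the same number correlated at 0.039 over all probe sets and 0.025 over the brighter 50%, across probe sets, which are not independent. The bacterial control RNAs did split the arrays by that number, so a fit with the replicate number as a block is given beside the main values.

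Alternatives planned before the data were examined were quantile normalization, subtraction of array medians, leaving out the dimmest 25% or 50% of probe sets, pseudocounts of 1 and 64, trended and robust moderation, array weights, the replicate block, leaving out each array in turn, other thresholds (adjusted p under 0.01 or 0.10, at least 2-fold, limma's treat against 1.2-fold), the mean of a gene's probe sets, leaving out probe sets that can match several transcripts, and pairwise folds of 1.5 and 3. The replicate block without the dimmest 50% of probe sets was added after the data were seen. Figures were drawn with matplotlib.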

Results

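Messenger RNA levels were measured in eye discs dissected from Drosophila melanogaster pupae about 40 h after pupariation, from animals raised at 29 °C. Control animals carried GMR-Gal4, a driver that expresses the yeast activator Gal4 in the developing eye. The other animals carried GMR-Gal4 together with UAS-Yki and so overexpressed Yorkie (Yki), the transcriptional coactivator that Hippo signalling restrains. Each group had 2 arrays, and the only comparison in the design sets the Yki arrays against the control arrays, to find which transcripts differ when Yki is raised in the eye. The deposited intensities had been scaled, with a trimmed mean of 500.01 on every array. Over the 18769 non-control probe sets the median intensity was 79.4 and 97.1 on the control arrays and 81.1 and 101 on the Yki arrays, and 22.2% to 28.3% of probe sets lay below an intensity of 16. The log2 values of replicate arrays correlated across probe sets at 0.975 in the control group and 0.973 in the Yki group, and arrays of different groups at 0.945 to 0.962. The labels do not say how many animals each sample pooled. The limma p-values of genes and probe sets rest on the spread between these arrays, moderated over all probe sets. Those of camera and of permutations across genes rest on the spread between genes, and do not measure replication between arrays. The 4 arrays limit the precision of every value.

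yki RNA measured 20.4-fold higher in Yki-overexpressing discs than in control discs, on arrays where its signal lay near the top of the scale. As groups, genes of cell division, Notch signalling, ribosome biogenesis and photoreceptor specification were lower in Yki discs, while genes of phototransduction, muscle, antioxidant enzymes and eye pigment were higher. Of 36 gene lists fixed before the data were examined, 13 passed the limma set test camera with its preset correlation, 5 higher and 8 lower. No list passed with an estimated correlation (smallest adjusted p = 0.777 with an estimated correlation) or in the rotation test fry (smallest adjusted p 0.175), so each shift below rests on the preset correlation. With an estimated correlation, camera found a simulated list shifted by 1 log2 unit in 0 of 20 runs. Its failure to pass a list therefore cannot count against a shift of that size. The list of known Yki target genes did not pass camera with either correlation, or fry, which ask for a shift in 1 direction.

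The overexpressed gene separated the groups on every array. yki had intensities of 1285 and 1261 on the control arrays and 26417 and 26183 on the Yki arrays, with means of 1273 ± 17.1 and 26300 ± 166 (SD, n = 2 each). The difference was 4.35 on the log2(value + 16) scale (SE 0.22), with a limma adjusted p of 0.0251 over genes and 0.0393 over probe sets. It was 4.35 within replicate 1 and 4.36 within replicate 2. Only 1 probe set was brighter than yki on each Yki array, so its intensity lay near the top of the scale, where the 20.4-fold difference can understate the change. An exact permutation test of 2 against 2 arrays cannot give a two-sided p below 0.333, the value found for yki. With any single array left out the difference stayed between 4.34 and 4.37, but its adjusted p over probe sets was 0.138 to 0.372, and the call was also lost with a pseudocount of 1.

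Of 11982 named genes, 12 passed an adjusted p of 0.05, 2 higher and 10 lower with Yki overexpression. Besides yki, CG9150 rose, from 69.3 ± 30.9 to 4379 ± 1562 (log2 difference 5.69, SE 0.40, adjusted p 0.0344). The largest fall was that of CG13460, from 3650 ± 289 in control discs to 8.69 ± 0.80 in Yki discs (log2 difference -7.21, SE 0.23, adjusted p 0.00621). CG12310 fell from 8636 ± 597 to 61.0 ± 31.9 (log2 difference -6.87, SE 0.35, adjusted p 0.0251). PGRP-SB2, of the peptidoglycan recognition protein family, fell from 3400 ± 1103 to 62.4 ± 13.5 (log2 difference -5.42, SE 0.32, adjusted p 0.0344). The other genes that fell were CG42717 (-5.29), CG17362 (-4.97), CG18649 (-4.62), CG34279 (-4.50), CG8087 (-4.39), nol (-3.97) and CG34276 (-3.82), with Yki means between 4.04 and 84.6. Several of these means lie below the pseudocount of 16, so the log2 differences understate the change. The 12 genes were called again with the replicate number as a block, where 65 genes passed, 24 higher and 41 lower. Fits without 1 array leave a single array in a group, so they cannot show whether these calls depend on 1 array.

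**Figure D1:**
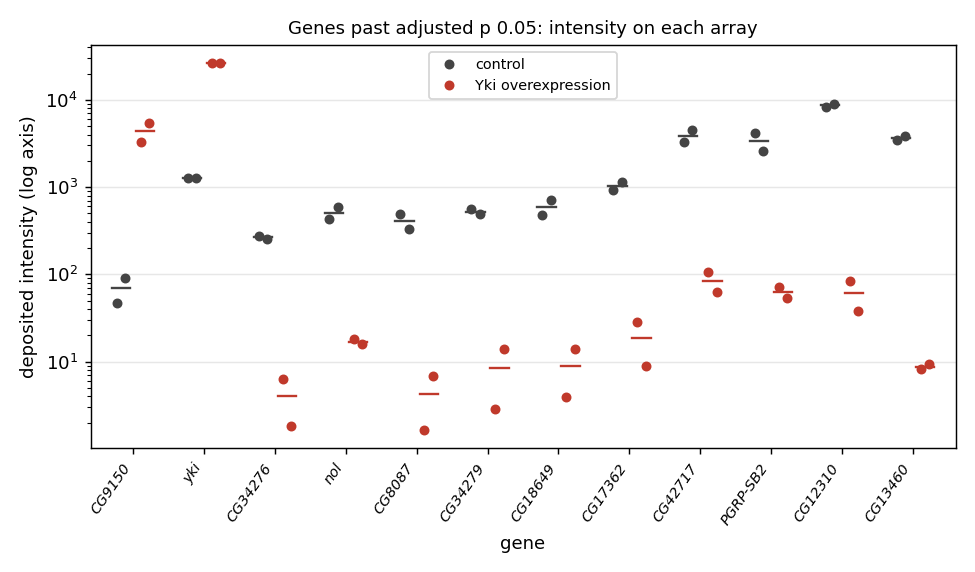
Deposited intensity (log axis) of the 12 genes past an adjusted p of 0.05 on each array; dots are arrays and bars the mean of the 2 arrays of a group. yki lies near 26300 on both Yki arrays against 1273 in control discs, and CG13460 lies below 10 on both Yki arrays.

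Over all 18769 non-control probe sets, 3 passed an adjusted p of 0.05: those of yki, CG13460 and CG12310, 1 higher and 2 lower. An unadjusted p under 0.05 was reached by 2472 probe sets, 1287 higher and 1185 lower, against 938 expected by chance. With array medians subtracted the count was 874, 441 higher and 433 lower, where the moderation of the variances pooled all probe sets to a single SD of 0.42. With the replicate block it was 27, 6 higher and 21 lower, and with any single array left out it was 0. In all 4 pairwise comparisons of a Yki array with a control array, 576 probe sets differed by at least 2-fold, 258 higher and 318 lower. The groups did not overlap for 45.3% of probe sets, where chance gives 33.3%.

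Cell division genes were lower in Yki discs. The cell cycle and DNA replication list had a median log2 difference of -1.07 over 51 measured genes, and 37 fell when adjusted over the list alone (34 with the replicate block), none rose and 14 did not pass. None of the 51 passed over all genes. Incenp, a subunit of the chromosomal passenger complex, fell from 817 ± 83.3 to 206 ± 6.38 (log2 difference -1.91, adjusted p 0.00653 over the list alone). Its partner borr had a log2 difference of -1.90, the replicative helicase subunit Mcm5 of -1.75 and the spindle checkpoint gene mad2 of -1.74, each past the threshold over the list alone. CycE, the S phase cyclin, had 654 ± 326 in control discs and 316 ± 12.8 in Yki discs, which did not pass (log2 difference -0.92, adjusted p 0.361). The list passed camera with an adjusted p of 3.5e-21 and not with an estimated correlation (adjusted p = 0.777 with an estimated correlation). Its median was -0.94 within replicate 1 and -1.26 within replicate 2, and the list passed in all 16 other settings tried with the preset correlation. Ribosome biogenesis genes were lower too, with a median of -0.57 over 24 genes (camera adjusted p 1.2e-06, adjusted p = 0.852 with an estimated correlation), and a median of -0.38 and -0.78 within the replicates. None of the 24 passed over the list alone, where 8 had an unadjusted limma p under 0.05, and 3 fell over the list alone with the replicate block. The snoRNP protein genes Nop10 and Fib had log2 differences of -1.27 and -1.24.

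Notch signalling genes, among them the Enhancer of split genes that Notch activates, were lower as well. Their list had a median log2 difference of -1.29 over 22 genes, and 12 fell when adjusted over the list alone, none rose and 10 did not pass. Among the Bearded family genes, E(spl)m4-BFM fell from 2019 ± 56.2 to 358 ± 114 (log2 difference -2.48), Tom from 4852 ± 154 to 1055 ± 147 (-2.19) and Brd from 1384 ± 213 to 304 ± 65.7 (-2.14). E(spl)m7-HLH, a basic helix-loop-helix repressor, fell from 1590 ± 53.9 to 352 ± 62.5 (-2.13). All of these had an adjusted p of 0.00237 over the list alone. The list passed camera (adjusted p 1.5e-08, adjusted p = 0.777 with an estimated correlation), with medians of -1.01 and -1.33 within replicates 1 and 2. No list member passed over all genes, but with trended and robust moderation E(spl)m4-BFM, Tom and E(spl)m7-HLH did (adjusted p 0.0423, 0.0382 and 0.0423).

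As lists, genes that specify photoreceptors and the measured genes of phototransduction went opposite ways. The photoreceptor specification list had a median log2 difference of -0.70 over 32 genes, of which 22 were below 0 and 10 above. When adjusted over the list alone, 13 fell, 1 rose (dpp, a secreted signal) and 18 did not pass. The homeobox gene ro fell from 185 ± 26.5 to 29.8 ± 33.5 (log2 difference -2.35), the proneural gene ato from 566 ± 55.5 to 155 ± 47.4 (-1.79), the receptor kinase gene sev from 263 ± 35.3 to 70.9 ± 16.3 (-1.69) and ss from 227 ± 8.88 to 65.1 ± 30.1 (-1.64). The list passed camera (adjusted p 0.000732, adjusted p = 0.852 with an estimated correlation), had medians of -0.28 and -0.78 within replicates 1 and 2, and lost its call without control replicate 2 (median -0.54, adjusted p 0.0552). The phototransduction list had a median of 0.90 over 31 genes, of which 30 were above 0. Its listed genes ninaE, Rh2, Rh3, Rh4, Rh5, Rh6, norpA, ninaC and ninaA, among others, were not analysed here. Over the list alone 2 rose, none fell and 29 did not pass. With the replicate block 8 rose. trp, a channel gene of the light response, rose from 507 ± 63.3 to 2251 ± 883 (log2 difference 2.06), and the photoreceptor dehydrogenase gene Pdh from 7245 ± 780 to 22761 ± 3804 (1.64), both with an adjusted p of 0.0288 over the list alone. The list passed camera (adjusted p 1.5e-09, adjusted p = 0.777 with an estimated correlation), with medians of 0.73 and 0.90 within the replicates.

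Eye pigment genes were also higher, with a median log2 difference of 0.17 and a mean of 0.63 over 23 genes (camera adjusted p 0.00649, adjusted p = 0.777 with an estimated correlation). The list's median was 0.36 within replicate 1 and 0.12 within replicate 2. Over the list alone 3 rose, none fell and 20 did not pass, and with the replicate block 6 rose. bw, a pigment precursor transporter, rose from 1059 ± 188 to 3041 ± 768 (log2 difference 1.49), cd from 626 ± 83.5 to 1755 ± 164 (1.47) and cn, an ommochrome pathway enzyme gene, from 38.8 ± 16 to 127 ± 17.7 (1.41). Neuronal and synaptic genes had a median of 0.42 over 31 genes (camera adjusted p 0.00035, adjusted p = 0.852 with an estimated correlation), but none passed over the list alone, where 1 had an unadjusted limma p under 0.05. Their median was 0.92 within replicate 1 and 0.06 within replicate 2, and the call was lost without control replicate 1 (median 0.17, adjusted p 0.20). The synaptic vesicle gene nSyb had 210 ± 60.1 and 393 ± 91.1 (log2 difference 0.86). elav, a pan-neuronal RNA-binding protein gene, had 2208 ± 1577 and 2187 ± 342, a log2 difference of 0.19 that became -0.61 without control replicate 1. Cone and pigment cell genes did not pass (21 genes, median -0.14, camera adjusted p 0.967), with an unadjusted p of 0.00035 in the mixed form of fry. In that list the lens gene Cpr72Ec had 8768 ± 503 and 19378 ± 2315 and the homeobox gene B-H2 960 ± 90.7 and 499 ± 16.1, neither past the threshold over that list alone (adjusted p 0.0749). B-H2 is also in the photoreceptor specification list, over which alone it fell (adjusted p 0.0316).

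**Figure D2:**
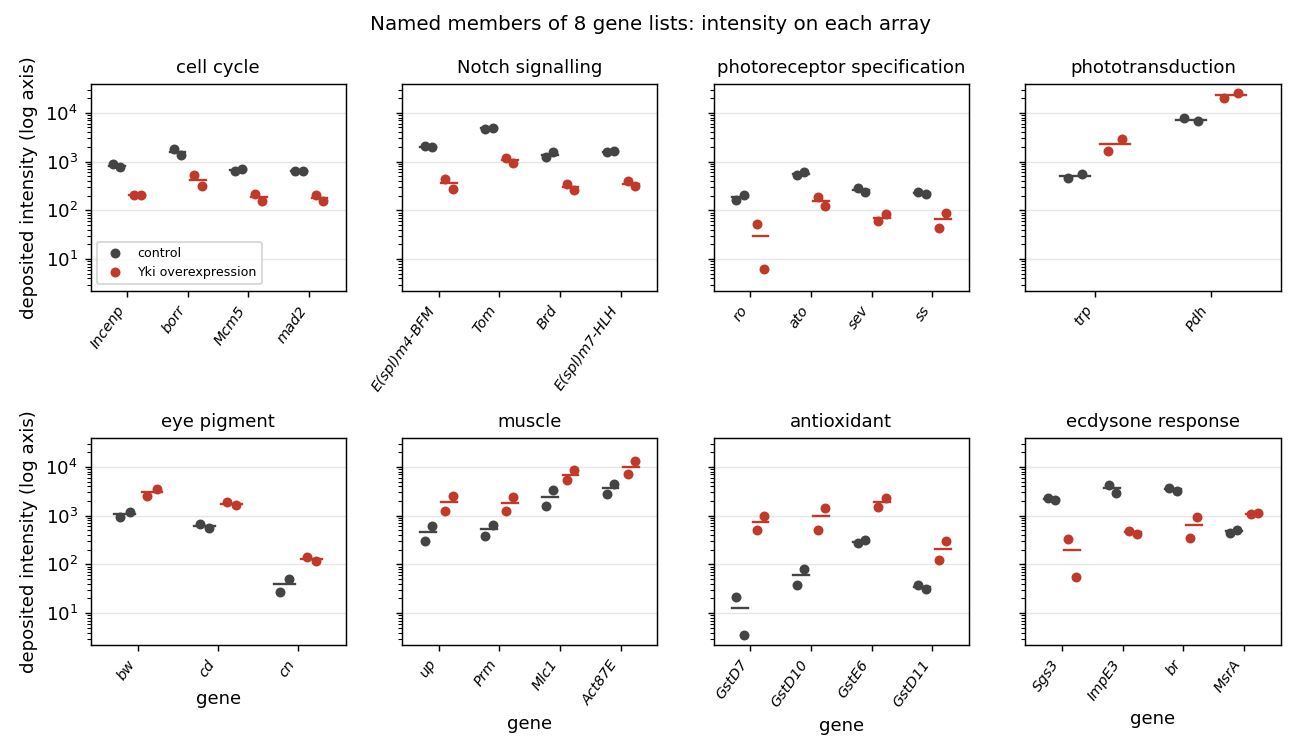
Deposited intensity (log axis) of the named members of 8 gene lists on each array; dots are arrays and bars the mean of the 2 arrays of a group. Incenp, Tom and ato lie lower on both Yki arrays, and trp, bw and GstE6 lie higher on both.

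Some genes of the ecdysone response and pupal timing list differed between the groups. This list, chosen as stage markers but including the salivary glue gene Sgs3, had a median log2 difference of -0.25 and a mean of -0.71 over 26 genes, with medians of -0.60 and -0.50 within replicates 1 and 2. Over the list alone 4 fell, 1 rose and 21 did not pass, and with the replicate block 5 fell and 2 rose. Sgs3 fell from 2170 ± 112 to 194 ± 198 (log2 difference -3.80), ImpE3 from 3610 ± 944 to 451 ± 48.7 (-2.93) and br, a transcription factor gene of the larval to pupal transition, from 3473 ± 393 to 650 ± 424 (-2.55). MsrA rose from 481 ± 50.9 to 1104 ± 11.5 (1.18). ImpE3 also passed over all genes with the replicate block (adjusted p 0.0368) and with trended and robust moderation (0.0338). The list passed camera (adjusted p 0.0178, adjusted p = 0.777 with an estimated correlation), but not without Yki replicate 1 (median -0.45, adjusted p 0.0567). Cuticle protein genes went both ways. Of 119, 9 rose and 6 fell when adjusted over the list alone and 104 did not pass, and with the replicate block 28 rose and 14 fell. Cpr49Aa rose from 232 ± 160 to 3070 ± 1952 (log2 difference 3.64) and Cpr62Bb from 1826 ± 1280 to 19099 ± 5518 (3.54), while Lcp65Ad fell from 13850 ± 6278 to 1122 ± 393 (-3.57) and Cpr65Ec from 6472 ± 5577 to 241 ± 103 (-4.39). Over all genes Cpr49Aa, Cpr62Bb and Lcp65Ad passed with the replicate block (adjusted p 0.0281, 0.0394 and 0.0292), and Lcp65Ad with trended and robust moderation (0.0423). The cuticle list had a median of 0.25 (-0.09 and 0.58 within replicates 1 and 2) and a camera adjusted p of 0.0567, which became 0.0149 with the replicate block, 0.00231 without control replicate 1 and 0.00183 without Yki replicate 1.

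Markers of other tissues differed between the groups as well. The muscle list had the highest median of the 36 lists, 1.27 over 22 genes, with 8 that rose over the list alone, none that fell and 14 that did not pass. With the replicate block 16 rose and 1 fell. The troponin T gene up rose from 455 ± 222 to 1885 ± 881 (log2 difference 2.02), paramyosin (Prm) from 521 ± 186 to 1844 ± 815 (1.76), the myosin light chain gene Mlc1 from 2454 ± 1204 to 6928 ± 2261 (1.54) and Act87E from 3641 ± 1277 to 10182 ± 4251 (1.46), each with an adjusted p of 0.0496 over the list alone. The muscle list passed camera (adjusted p 2.3e-08, adjusted p = 0.852 with an estimated correlation), with medians of 1.36 and 1.35 within the replicates. The tracheal and antennal list was lower, with a median of -0.65 over 14 genes and 2 that fell over the list alone, ato and ss, which also stand in the photoreceptor specification list. It passed camera (adjusted p 0.0189, adjusted p = 0.777 with an estimated correlation), had medians of -0.44 and -0.62 within the replicates, and lost its call without Yki replicate 1 (median -0.57, adjusted p 0.0824). Brain and optic lobe genes did not pass as a list (30 genes, median 0.05, camera adjusted p 0.635), but the neuroblast genes dpn (553 ± 28.4 and 119 ± 11.1, log2 difference -2.08), ase (-1.79) and mira (-1.67), and dac (-1.42), fell over the list alone. With the replicate block 5 fell and 1 rose. Among glial markers (16 genes, median 0.04, camera adjusted p 0.315) moody, a receptor gene of the blood-brain barrier, rose over the list alone from 2488 ± 298 to 7071 ± 819, and with the replicate block 1 rose and 1 fell. Haemocyte genes (19, median -0.10, adjusted p 0.943) and fat body genes (16, median -0.07, adjusted p 1.0) did not pass.

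Antioxidant enzyme genes were higher as a list, with a median log2 difference of 0.46 over 46 genes and 5 that rose, 1 that fell (Prx6a, a peroxiredoxin gene) and 40 that did not pass over the list alone. The 5 that rose encode glutathione S-transferases, detoxifying enzymes. Listed genes such as Sod1, Prx5, Jafrac1, Jafrac2, Gss1 and Gss2 were not analysed here, so the list covers only part of the antioxidant enzymes. GstD7 rose from 12.6 ± 12.9 to 731 ± 325 (log2 difference 4.71), GstD10 from 59.2 ± 29.9 to 983 ± 672 (3.61), GstE6 from 293 ± 23.5 to 1910 ± 607 (2.61) GstD11 from 34.4 ± 3.98 to 210 ± 121 (2.06) and GstD9 by 1.72. With the replicate block GstD7, GstD10 and GstE6 also passed over all genes (adjusted p 0.0482, 0.034 and 0.0485), GstD7 and GstE6 did with trended and robust moderation (0.0403 and 0.0423), and 8 genes of the list rose and 2 fell over the list alone. The mitochondrial superoxide dismutase gene Sod2 had 3097 ± 414 and 3703 ± 638, which did not pass (log2 difference 0.25, adjusted p 0.709). The antioxidant list passed camera (adjusted p 0.000259, adjusted p = 0.852 with an estimated correlation), with medians of 0.25 and 0.46 within the replicates. Innate immunity genes did not pass as a list (27 genes, median 0.21, camera adjusted p 0.372). Over the list alone 5 rose and 3 fell, and with the replicate block 6 rose and 3 fell. PGRP-SB2 was among those that fell, and the Bomanin genes BomS4, BomS2 and BomT3, which encode immune-induced peptides, rose over the list alone by 2.63, 2.24 and 2.15.

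Mitochondrial genes showed small differences. Subunits of complex I (32 genes, median log2 difference 0.12, camera adjusted p 0.26), of complexes II to V (43 genes, median 0.13, adjusted p 0.174) and genes of mitochondrial dynamics and quality control (22 genes, median 0.06, adjusted p 0.809) did not pass. Without control replicate 1 the list of complex I passed (median 0.23, adjusted p 0.0313), and that of complexes II to V passed without control replicate 1 (median 0.28, adjusted p 0.0394) and without Yki replicate 1 (median 0.26, adjusted p 0.0382). COX7AL2, of complex IV, rose from 336 ± 9.52 to 1062 ± 137 when adjusted over its list alone (log2 difference 1.61, adjusted p 0.0416), which it did not pass with the replicate block. No other gene of these 3 lists passed over its list alone. The fusion genes Opa1 and Marf were not called. Opa1 had 768 ± 51.3 and 1092 ± 113 (log2 difference 0.50, SE 0.23, adjusted p 0.398), and Marf 917 ± 19.7 and 1107 ± 39.5 (0.27, SE 0.22, adjusted p 0.629), with both Yki arrays above both control arrays for each. Such a separation was common: 4553 of 18769 non-control probe sets were higher in this way. In the list of these genes 5 of 22 were higher and 4 lower without overlap. Mitochondrial ribosomal proteins were lower as a list (69 genes, median -0.21, camera adjusted p 0.00796, adjusted p = 0.926 with an estimated correlation), with medians of -0.32 and -0.10 within the replicates and no member past the threshold over the list alone, where 3 had an unadjusted limma p under 0.05. That call was lost with quantile normalization (median -0.12, adjusted p 0.141), without control replicate 1 (-0.08, 0.698) and without Yki replicate 2 (-0.16, 0.156). Regulators of mitochondrial biogenesis were also lower (11 genes, median -0.41, -0.25 and -0.64 within the replicates, camera adjusted p 0.0272, adjusted p = 0.852 with an estimated correlation). Over the list alone 1 gene fell, mtSSB, which binds single-stranded mitochondrial DNA, from 1552 ± 273 to 630 ± 85.8, which did not pass with the replicate block. The call of this list was lost with quantile normalization (median -0.29, adjusted p 0.0792), without control replicate 1 (-0.49, 0.0759), without control replicate 2 (-0.34, 0.0626) and without Yki replicate 2 (-0.24, 0.347).

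The target genes of Yki measured here did not move in 1 direction as a group. Their list had a median log2 difference of -0.06 over 17 measured genes (camera adjusted p 0.628), 8 above and 9 below 0. None passed over the list alone, where 4 had an unadjusted limma p under 0.05, 1 higher and 3 lower. The mixed form of fry, which asks whether members move in either direction, gave this list an unadjusted p of 0.00088. That test also gave low unadjusted p-values for lists of other kinds, such as 0.0042 for tracheal and antennal genes and 0.031 for glia. For others, such as complex I (0.50), it did not. A low value therefore does not set the Yki targets apart. ex, an upstream Hippo component and Yki target, had 360 ± 0.51 and 292 ± 14.8 (log2 difference -0.29, SE 0.22, adjusted p 0.599). The Golgi kinase gene fj had 1089 ± 31.8 and 663 ± 40.4 (-0.70, SE 0.22, adjusted p 0.26), kibra 131 ± 39.0 and 266 ± 56.6 (0.95, SE 0.31, adjusted p 0.268) and the Notch ligand gene Delta 2704 ± 879 and 1087 ± 182 (-1.27, SE 0.32, adjusted p 0.197). Delta fell over the Notch list alone. The target genes Diap1 and Myc, and the rhodopsin gene ninaE, were not analysed here. Nor were the listed targets dachs, dally, vn, upd3, Ser, wg, E2f1, Fas2, fz3, arm and Cdh74A, so the list covers only part of the known targets. Hippo pathway components did not pass either (33 genes, median -0.04, adjusted p 0.822), nor did apoptosis genes (21 genes, median -0.20, adjusted p 0.188), among which the checkpoint kinase gene lok had 709 ± 7.76 and 304 ± 59.8 and the initiator caspase gene Dronc 1316 ± 209 and 871 ± 75.6.

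The other signalling and metabolic lists did not pass camera. Wingless and Dpp signalling genes (14, median log2 difference -0.33, adjusted p 0.14) included vg, Wnt6 and salm, which fell over the list alone by 1.61, 1.45 and 1.25, and dpp, which rose by 1.27. JNK and damage response genes (20, median 0.07, adjusted p 0.188) included scaf, which rose over the list alone from 5129 ± 837 to 14482 ± 29.8, and the filamin gene cher, from 654 ± 59.0 to 1408 ± 70.1. EGFR signalling (19 genes, median -0.17, adjusted p 0.256) passed without control replicate 1 (median -0.29, adjusted p 0.0227). The remaining medians were -0.25 for JAK/STAT signalling (9 genes, adjusted p 0.188), -0.14 for glycolysis (11, 0.597), 0.02 for cytosolic ribosomal proteins (41, 0.822), 0.22 for heat shock and stress (10, 0.188), 0.17 for junctions and polarity (31, 0.198), -0.07 for chitin synthesis (26, 0.644) and -0.20 for transcripts that differ between the sexes (8, 0.822). Without control replicate 1 the chitin synthesis list passed as higher (median 0.23, adjusted p 0.0425). Median, mean and test direction differed in sign for 6 lists that did not pass: brain and optic lobe, chitin synthesis, cytosolic ribosomal proteins, Hippo components, fat body and the transcripts that differ between the sexes.

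**Figure D3:**
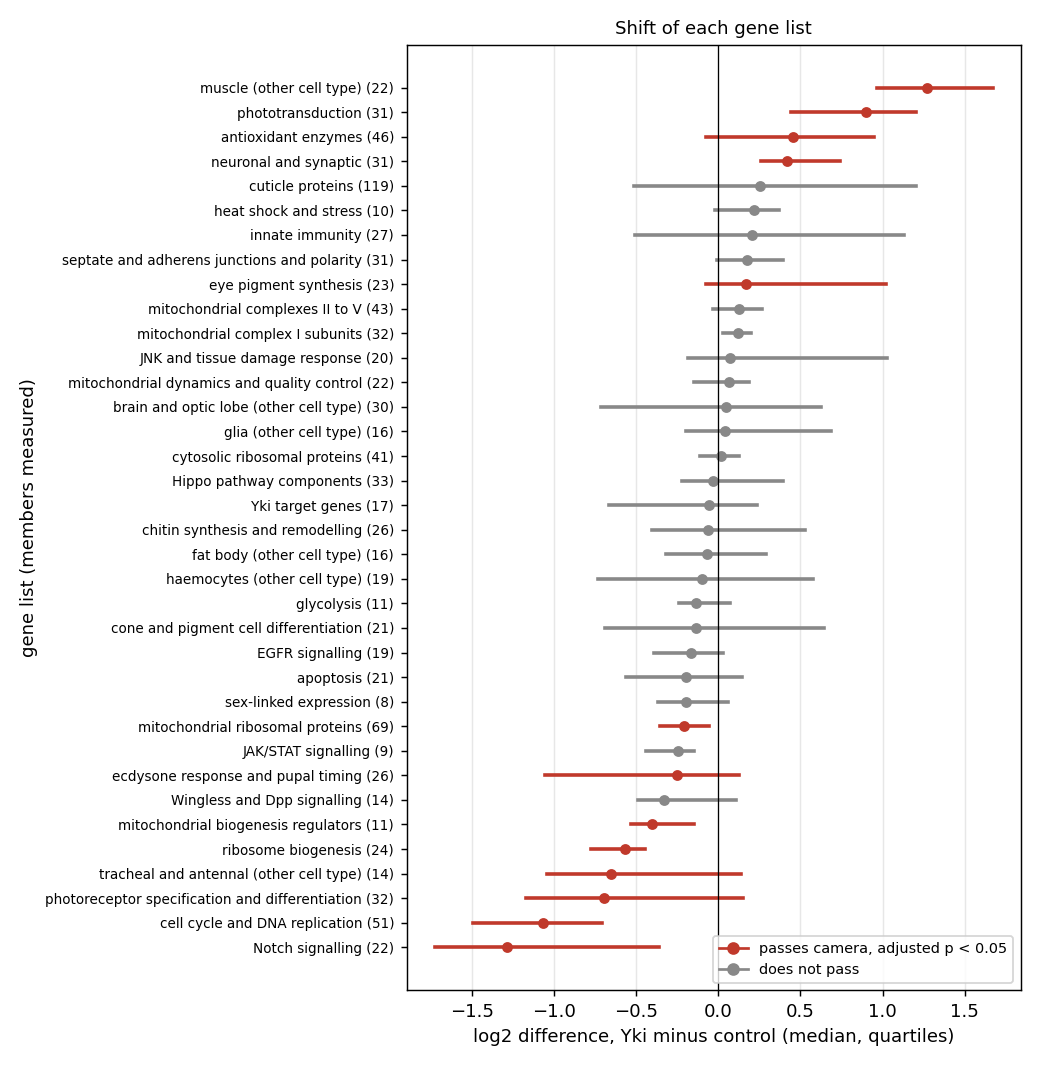
Median (dot) and quartiles (bar) of the log2 difference, Yki minus control, over the members of each of the 36 gene lists, with the number of measured members in brackets; red lists pass camera with its preset correlation. The medians run from -1.29 for Notch signalling to 1.27 for muscle.

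The control RNAs on the arrays split the samples by replicate number. The 24 probe sets for the bacterial RNAs dap, lys, phe and thr, which are added before labelling, had a median intensity of 448 on control replicate 1 and 260 on Yki replicate 1, but 6.08 on control replicate 2 and 7.41 on Yki replicate 2. The 18 probe sets for the hybridisation controls had medians between 1347 and 1888 on all 4 arrays. Each replicate number holds 1 array of each group, so the values within replicates and with the replicate block above compare arrays with similar levels of these controls. A block cannot move any mean log2 difference in this balanced layout, and all 13 lists that passed camera also passed with it. The 3' to 5' ratio of the actin control probe sets, a sign of RNA quality, was 2.35 and 2.16 on the control arrays and 1.82 and 2.36 on the Yki arrays. That of the GAPDH probe sets was 2.27 and 1.96 against 2.76 and 2.28, and that of the eIF4a probe sets 5.85 and 4.94 against 4.4 and 5.85.

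**Figure D4:**
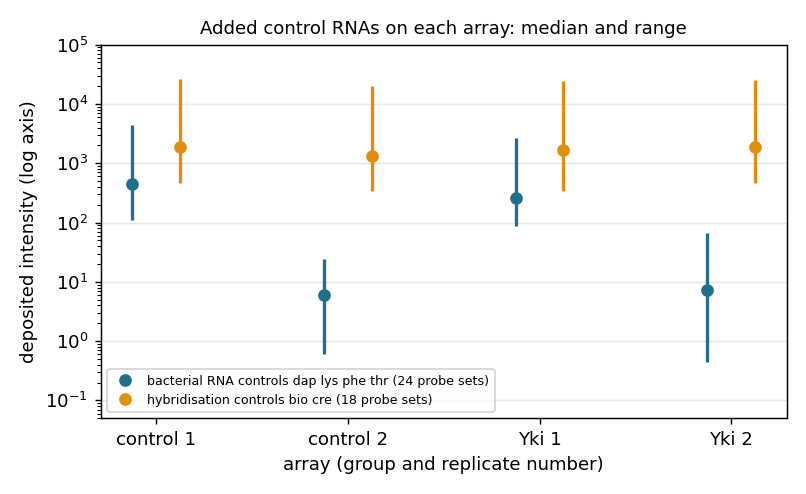
Median (dot) and range (line) of the deposited intensity (log axis) of 24 bacterial RNA control probe sets and 18 hybridisation control probe sets on each array. The bacterial controls lie at a median of 448 and 260 on the replicate 1 arrays and at 6.08 and 7.41 on the replicate 2 arrays.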

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

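The replicate block without the dimmest 50% of probe sets was chosen after the control RNAs were seen; the other alternatives were planned. The number of probe sets past the threshold moved with the processing: the 3 probe sets and 12 genes of the report became 12 (3 higher, 9 lower) and 20 with quantile normalization, 874 (441, 433) and 794 with array medians subtracted, 45 (14, 31) and 37 without the dimmest 25% of probe sets, 82 (24, 58) and 69 without the dimmest 50%, 20 (6, 14) and 58 with trended and robust moderation, 27 (6, 21) and 65 with the replicate block, and 318 (154, 164) and 265 with the block and without the dimmest 50%. With a pseudocount of 64 they became 2 (1, 1) and 2. With a pseudocount of 1, limma called 0 probe sets (0 higher, 0 lower) and 0 genes, with 2192 probe sets at an unadjusted p under 0.05; yki kept its difference (4.37) and lost its call. The stricter adjusted p of 0.01 left 1 (0 higher, 1 lower) and 1 gene, and the looser 0.10 gave 41 (13, 28) and 80. The mean of a gene's probe sets gave 27 genes. Array weights, a 2-fold minimum and limma's treat left 3 and 12. The 12 genes were all called with quantile normalization, subtracted medians, the 25% filter, trended moderation, array weights, the block and the mean of probe sets. With the 50% filter the 10 of them that it leaves in were called, and CG8087 and CG34276 were not tested. Of the 91 other named genes, 54 gained a call over all genes with array medians subtracted, 31 with the block and without the dimmest 50%, 10 without the dimmest 50%, 7 with the block, 7 with trended and robust moderation, 2 without the dimmest 25% and 2 with the mean of probe sets; the report gives those of the block and of trended moderation by name. Apart from the filters, which test fewer probe sets, the cause of these moves was not tested.

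Leaving out any single array, with the lone array of its group assumed to vary like the other group, gave 0 calls in limma for probe sets (0 higher, 0 lower) and genes, with 1486 to 2635 probe sets at an unadjusted p under 0.05. The difference of yki then ranged from 4.34 to 4.37, so a loss of calls in these fits cannot show that a call depends on 1 array. Probe sets at least 2-fold apart in all pairwise comparisons numbered 965 to 1463 without 1 array, where fewer comparisons are asked for, 1150 with a pseudocount of 1, 360 with 64, 1505 at 1.5-fold and 185 at 3-fold, against 576.

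Of the 13 lists past the set test, 7 passed in all 16 other settings with the preset correlation and 6 were lost in some, which the report names for left-out arrays and quantile normalization. With array medians subtracted the list of mitochondrial ribosomal proteins had an adjusted p of 0.148 and that of mitochondrial biogenesis regulators 0.174. The latter was also lost without the dimmest 50% of probe sets (0.153), and both were lost when the block was added to that filter (0.0627 and 0.188). With an estimated correlation 0 of 36 lists passed camera and 0 passed fry. The cuticle list passed in 8 settings. Wingless and Dpp signalling passed without probe sets that can match several transcripts (median -0.34, adjusted p 0.0241), and complexes II to V without the dimmest 50% (0.14, 0.036) and with a pseudocount of 64 (0.12, 0.0422).

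Medians that changed sign belonged to lists that did not pass. They were those of mitochondrial dynamics (-0.063), cytosolic ribosomal proteins (-0.10) and brain and optic lobe (-0.017) with quantile normalization, cytosolic ribosomal proteins (-0.018) with medians subtracted, JNK signalling without the dimmest 25% (-0.012) or 50% (-0.068), with the block added to the latter (-0.068) and without probe sets that can match several transcripts (-0.088), and Hippo components (0.014), chitin synthesis (0.25) and the gene aPKC (0.014) with the mean of a gene's probe sets. Over left-out arrays the ranges that crossed 0 were -0.23 to 0.15 for Yki targets, -0.31 to 0.059 for glycolysis, -0.10 to 0.23 for chitin synthesis, -0.0069 to 0.27 for glia, -0.24 to 0.024 for fat body, -0.31 to 0.22 for brain and optic lobe, -0.61 to 0.98 for elav, -0.080 to 0.042 for Hippo components, -0.43 to 0.18 for cone and pigment cells, -0.29 to 0.019 for EGFR signalling, -0.022 to 0.23 for complex I, -0.11 to 0.16 for cytosolic ribosomal proteins and -0.060 to 0.24 for haemocytes. The cause was not tested. Quantile normalization moved the median difference of all probe sets from 0.04 to -0.00. Between 22.2% and 28.3% of probe sets per array lay below the pseudocount, and differences there are understated.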

Other observations

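The tests of labelling batch, array scaling, Yki targets and muscle, the list of glue and late larval genes, and the test of neighbouring genes were chosen after the results they concern were seen. Several genes of the late larval salivary gland had much RNA in the control samples, while others, such as ng4 and Eig71Ei, had little. The glue gene Sgs7 had 11010 and 9347 on the control arrays and 799 and 187 on the Yki arrays. A list of 21 glue and late larval genes had a median log2 difference of -3.43, with 16 genes lower on both Yki arrays than on both control arrays, a description only, since the list was chosen from these values. Over all probe sets the groups did not overlap for 45.3%, both directions together, where chance gives 33.3%. Salivary gland RNA in the control samples may contribute. Other genes of that gland, listed before their values were seen, had a median of -0.45 over 8 genes (quartiles -1.19 and 0.34; 0.10 within replicate 1 and -0.97 within replicate 2). PH4alphaSG1, PH4alphaSG2 and Scr were lower on both Yki arrays, while pip (2602 ± 1397 and 4780 ± 530) and Papss were higher, so the question stays open. A difference in stage, at which glue genes are shut off, was not tested for these genes.

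Cell division and early eye genes were lower in Yki discs and light response genes higher. Array scaling does not account for it as a whole, since the cell cycle list kept a median of -1.06 after quantile normalization. A labelling batch that follows the replicate number is shared by 1 array of each group and by itself gives no difference between them, yet the list's median was -0.94 within replicate 1 and -1.26 within replicate 2. Younger tissue in the control samples may explain part of the pattern. In lists written before their values were seen, the median of 8 late retina genes lay 1.13 above that of 10 early eye genes (0.85 against -0.28; exact permutation across genes p 0.0482, 43758 orders, which treats genes as independent). On the early list hh (1.78), ptc (1.15) and hry (0.23) went the other way, and emc (-0.06) and da (-0.005) hardly moved. On the late list pinta (-0.21) went the other way. These lists hold genes of the same kinds as those that showed the pattern, so they cannot by themselves tell its cause. Yki overexpression itself stays open too. The Yki target list had a median of -0.058 (quartiles -0.67 and 0.24, camera adjusted p 0.628), and its members went both ways. The design ties any difference in stage to genotype, so a delay of the controls and an effect of Yki on the timing of the eye cannot be told apart here.

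Muscle genes were higher in Yki discs. More muscle tissue in the Yki samples may be the source, and 81.0% of the abundant members, 17 of 21, were higher on both Yki arrays than on both control arrays. sls, tn, Zasp52 and Zasp66 were not. Over all 18769 non-control probe sets, 4553 were higher on both Yki arrays than on both control arrays. The count of muscle genes uses the same genes and values that showed the pattern, so it cannot decide the question, which stays open. No biological explanation was tested for this pattern.

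Genes that differed at least 2-fold in all pairwise comparisons lay next to each other more often than random draws of genes. Neighbours were taken in the order of the 11890 measured genes that could be placed, so unmeasured genes can lie between them. Among 277 lower genes there were 29 adjacent pairs, against a mean of 6.45 and a highest count of 19 in 10000 draws, and among 200 higher genes 12, against 3.32 and 11 (one-sided permutation p 0.0001 for each, the smallest these draws can give). The longest run of lower genes held 6, Eig71Ea, CG43084, Eig71Ed, Eig71Ee, Eig71Ef and Eig71Eg, and the next held 4, E(spl)m2-BFM, E(spl)m3-HLH, E(spl)m4-BFM and E(spl)m5-HLH. The draws took no account of gene families that lie together, such as these, so their p-values do not measure more than that. The other splits of the 4 arrays into pairs are too few for a share under 0.05: the real split gave 576 probe sets at least 2-fold apart in all pairwise comparisons and the highest other 33.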
